A study of Mus musculus with 10 samples.

How the data were processed

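The samples were C2C12 mouse myoblasts, a line that stops dividing and fuses into multinucleated myotubes when serum is lowered. Per the labels, cells were kept in growth medium with 15% fetal bovine serum and switched at 90 to 100% confluence to differentiation medium with 3% horse serum. Adenovirus was added at day 1 of differentiation and carried either lacZ, as the control, or dnMEK5, a dominant negative form of the kinase MEK5, which activates ERK5. The 5 groups were growth medium at day 0, lacZ at days 2.5 and 4.5, and dnMEK5 at days 2.5 and 4.5. Each group had 2 arrays, 1 from each of 2 independent experiments, which makes 10 arrays. Day 0 cells were not infected, so medium, time and infection change together between day 0 and the lacZ groups.

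Per the labels, 5 µg of total RNA per array was labelled with biotin and hybridized to Mouse Genome 430 2.0 arrays. The series design text names GCOS 1.4 and GeneSpring GX 11.0.2 for image and data analysis, and the submitters' processing notes name GCRMA. The version and settings of GCRMA are not given in the sources used here. The table of values deposited by the authors holds the intensity of each probe set on a linear scale, already normalized across arrays, from 1.95 to 48623 over 45101 probe sets. A table deposited beside it holds log2 ratios. From the values, each ratio is that array over the day 0 array with the same replicate number, matched in every cell within 3e-06. All columns of both tables were matched to samples, with 0 left unmatched.

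Log2 of the deposited intensity was taken, and probe sets with a log2 value of at least 5 on at least 2 of the 10 arrays were kept, which left 18235. Of these, 16757 were annotated to a single gene symbol, and 1478 with several symbols or none were left out. Each gene was represented by its probe set with the highest mean over the 10 arrays, giving 9575 genes. Gene symbols came from the array annotation and were checked by gene ID against a RefSeq table, which changed 0 symbols.

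The 5 group means were fitted in 1 model over all 10 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. P-values were two-sided and adjusted over all genes by the Benjamini-Hochberg method. A gene passed at an adjusted p below 0.05. The main comparisons were dnMEK5 against lacZ at each day and lacZ at each day against day 0. Secondary comparisons were lacZ at day 4.5 against lacZ at day 2.5, and the difference of the dnMEK5 effect between the days as an interaction contrast. Errors given with log2 fold changes are limma's moderated standard errors. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

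The fit had 5 residual degrees of freedom and 3.10 prior degrees of freedom, with a median residual SD of 0.190. With 2 arrays per group, the number of arrays limits the precision. Where the lower group mean of a gene lies under log2 5, its level there was not told apart from background, so the size of the change is a lower bound and its rank is not read. All arrays had similar signal over background, since between 37.0 and 38.3% of probe sets had a log2 value of at least 5 on each. Replicate arrays correlated across probe sets kept at r = 0.980 to 0.986, a correlation across genes, which are not independent replicates.

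The replicate numbers pair the arrays by experiment. The pairing comes from the series design text, which gives 2 independent experiments of 5 samples each, and from the deposited ratios, which use the day 0 array of the same number. The values carry the same pairing: the differences between replicate arrays correlated between groups at r = 0.392 to 0.804 over the 10 pairs of groups. The design text names no statistical test and no block, so the fit fixed in advance had none and leaves this pairing out. The alternative with the experiment as a block had a median residual SD of 0.120, and its values stand beside a result where they change the call of a named gene or list, or move the gene count of a comparison by more than 1.5 times. Data were simulated from the fit with the block, with its spread, an additive difference between experiments and independent genes. With 200 changed genes among 9575, the fit without a block recovered 56.3% of changes of log2 1 and 95.2% of log2 2. Of its calls 0.460% were false. With the block the corresponding values were 96.9, 100 and 5.56%. The simulation held the block's own model, so it cannot show which fit suits the real data better. In the real data the pairing and the smaller residual SD speak for the block. With it, 1931 genes were higher and 1879 lower in experiment 2. Calls without the block therefore leave a real difference between experiments in the spread.

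The comparisons, the filter, the gene lists, the rule for named genes and all alternatives but the 3 that leave out Map2k5 were fixed before the data were examined. For each main comparison the rule names the 10 genes with the largest change in each direction among those that passed and whose arrays did not overlap between the groups. For each secondary comparison it names 5. Where fewer than 3 genes passed in a direction, the 5 with the smallest unadjusted p are named as not passing. Clone-type and predicted symbols are passed over, and Map2k5, Mapk7, Klf2, Klf4 and Npnt are always given. Up to 4 members of each gene list with the largest change may serve as examples.

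In all, 34 gene lists were fixed, and 33 were tested. The macrophage and leukocyte markers had too few measured members. Lists covered the ERK5 pathway and its reported targets, the Klf and Sp factors, immediate early genes, muscle regulators and structure, cell cycle, metabolism, stress, matrix and signalling, and markers of other cell types. Lists were tested with limma's camera at the preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether a list's genes changed more than the other genes, and calls were repeated with a correlation estimated per list. On data simulated with independent genes, a list of 30 genes all shifted by log2 0.5 had an unadjusted camera p below 0.05 in 10 of 10 simulations. That does not cover lists of correlated genes, smaller shifts or the adjustment over the lists. Member counts are given over all genes tested and adjusted over the list alone.

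Correlations of fold changes across genes carry no p-value, since genes are not independent replicates. Where comparisons shared the lacZ arrays, they were set beside 100 simulations of unchanged groups. The alternatives were the replicate block, no filter, a log2 floor of 7, quantile normalization, median centring, the deposited ratio table, the mean of a gene's probe sets, each probe set by itself, eBayes with trend and robust, only the arrays compared, a 2-fold minimum, leaving out each array in turn, and for lists the estimated correlation and fry. Leaving out Map2k5 from the agreement of the dnMEK5 effects, from their relation to differentiation and from the ERK5 list makes up those 3, added after seeing the data, because its own differences were far larger than those of any other gene. All alternatives other than the block were fitted without it. Groups of 2 arrays are too small for a count of other splits of the samples.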

Results

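The study asks which genes of differentiating C2C12 cells depend on the ERK5 pathway. Cells infected with dnMEK5 were therefore compared with cells infected with lacZ on the same day, and the lacZ cells with uninfected cells at day 0.

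Klf2 fell in dnMEK5 cells at day 2.5, by log2 -3.71 ± 0.27 against lacZ (n = 2 arrays per group, limma adjusted p = 0.00219). Klf2 encodes a Krüppel-like transcription factor. Its mean log2 intensity was 7.17 at day 0, 9.67 in lacZ cells and 5.96 in dnMEK5 cells. Hdc, the histidine decarboxylase that makes histamine, fell by at least 3.31 ± 0.20 on the log2 scale, to a mean of 3.16 (adjusted p = 0.00075). Cd55, a cell surface inhibitor of complement, fell by 2.50 ± 0.29 (adjusted p = 0.0331), and Serpinb9b, of a family of protease inhibitors, by 2.06 ± 0.21 (adjusted p = 0.0233). Pappa, a metalloproteinase that cleaves IGF-binding proteins, rose by at least 2.20 ± 0.24, from a mean of 3.26 (adjusted p = 0.0317).

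Map2k5, the gene for MEK5, stood at a mean log2 intensity of 14.98 in dnMEK5 cells and 7.62 in lacZ cells, a log2 difference of 7.37 ± 0.23 (adjusted p = 8.57e-06), or 165-fold. The virus carried a form of MEK5. Map2k5, also where it is counted among higher genes, is therefore not read as a response of the cells. Mapk7, the gene for ERK5, differed by -0.23 ± 0.13 and did not pass. Klf4, another Krüppel-like factor, differed by -2.04 ± 0.26, with an adjusted p of 0.0597 that became 0.000799 with the replicate block and ranged up to 0.708 over 16 alternatives, of which 4 passed. Npnt, which encodes nephronectin, an integrin ligand of the matrix, differed by -0.72 ± 0.25 and did not pass with or without the block (blocked adjusted p = 0.0692). Among the genes of smallest unadjusted p that did not pass were Smyd1, a muscle-specific methyltransferase (1.16 ± 0.16, adjusted p = 0.0871, 0.0121 with the block), Postn, a matrix protein (0.83 ± 0.19), and Dbh, dopamine beta-hydroxylase (0.67 ± 0.18).

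In total, 2 genes were higher and 4 lower in dnMEK5 cells at day 2.5 out of 9575, and 298 genes had an unadjusted p under 0.05, where chance alone gives 478.75. With the replicate block 4 were higher and 35 lower, and 803 had an unadjusted p under 0.05. Without the block the difference between experiments stays in the spread. The unblocked counts, here and below, can thus lie under the chance figure even where genes changed. Each of the 6 differences had the same sign in both experiments, which passing the test with 2 arrays per group nearly requires, so it adds no support. Map2k5 and Hdc passed in all 16 alternatives. Klf2 passed in 14, including without any 1 of the 10 arrays, and did not pass with no filter (adjusted p = 0.0827) or with only the arrays compared (0.19). The other 3 rested on most arrays and choices: over 16 alternatives Cd55 passed in 4, Pappa in 5 and Serpinb9b in 8. Without lacZ day 2.5 replicate 2 adjusted p was 0.308 for Cd55 and 0.289 for Pappa and Serpinb9b. With only the arrays compared it was 0.591 for Cd55 and Pappa and 0.19 for Serpinb9b, and with no filter 0.219, 0.219 and 0.161.

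**Figure D1:**
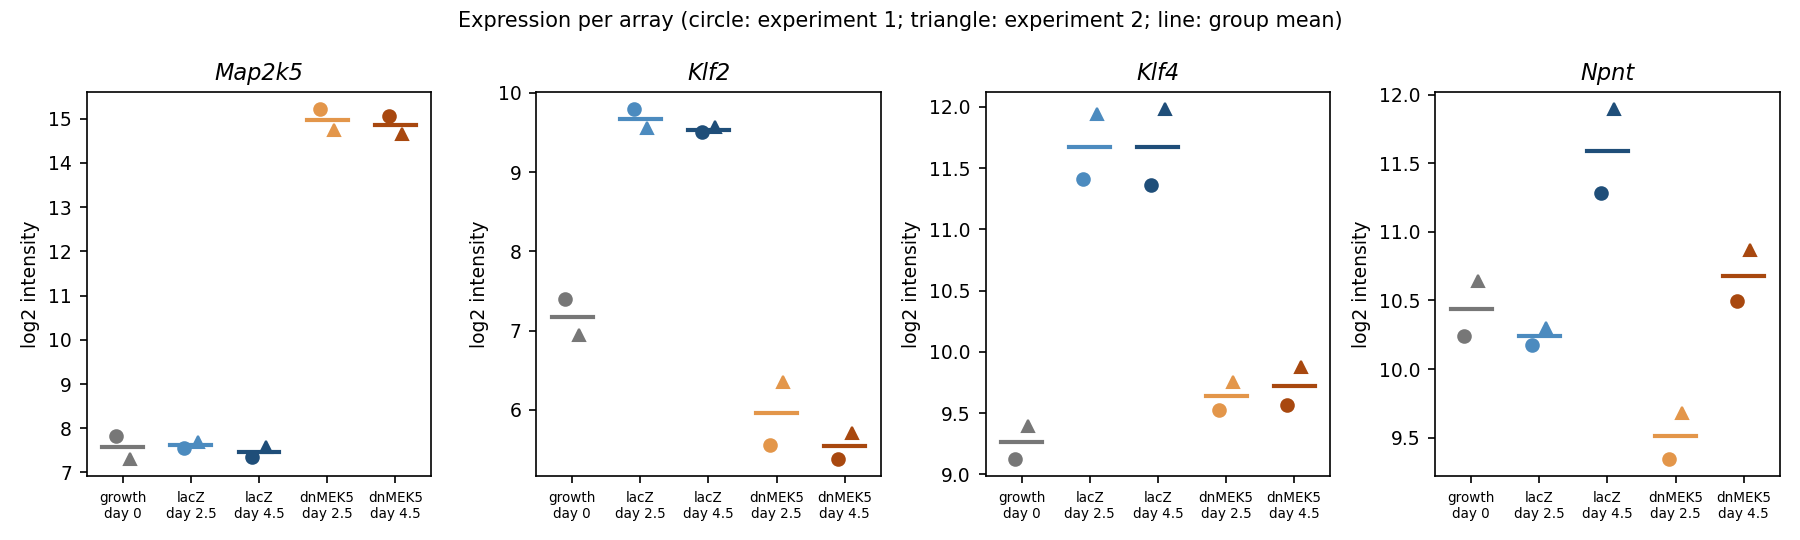
Log2 intensity (y axis) of Map2k5, Klf2, Klf4 and Npnt on each of the 10 arrays, by group (x axis). Circles are experiment 1, triangles experiment 2, and lines group means; in dnMEK5 cells the Klf2 means are 5.96 and 5.55, against 9.67 and 9.54 in lacZ cells.

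Of the 17 Klf and Sp transcription factors measured at day 2.5, Klf2 fell and 16 did not pass; adjusted over the list alone, 2 fell. The list's median was -0.13, and camera placed it below the other genes (adjusted p = 0.00224; adjusted p = 0.413 with an estimated correlation). Klf12 (-0.80) and Klf6 (-0.46) were the next members. No member of the 20 ribosome biogenesis genes passed over all genes or adjusted over the list alone, yet all 20 had positive differences, with Polr1b at 0.56 and Dkc1 at 0.46. The list's median was 0.22 (camera adjusted p = 2.85e-11; adjusted p = 0.131 with an estimated correlation). Cholesterol synthesis genes lay below 0 in 18 of 20 cases, with a median of -0.22 and Tm7sf2 at -0.46 and Hsd17b7 at -0.44 (adjusted p = 0.000357; adjusted p = 0.348 with an estimated correlation). Heat shock and NRF2 response genes had a median of 0.18, with 0.29 in experiment 1 and 0.05 in experiment 2, and with Hspa1b at 1.49 and Hsph1 at 1.31 (adjusted p = 6.29e-05; adjusted p = 0.348 with an estimated correlation). No member of these last 2 lists passed, over all genes or adjusted over the list alone.

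The immediate early genes (13 measured, median -0.13, Dusp1 at -0.76 and Jun at -0.45) and the matrix proteases and inhibitors (13 measured, median -0.13, with -0.04 in experiment 1 and -0.16 in experiment 2, Adam8 at -1.43) each had a camera adjusted p of 0.0433. Each had an adjusted p of 0.348 with an estimated correlation, and the replicate block gave 0.0988 and 0.0541. No member of either list passed, over all genes or adjusted over the list alone. Of the 14 members of the ERK5 pathway list, Map2k5 rose and Klf2 fell; adjusted over the list alone, 1 rose and 2 fell. Its median was -0.07 and the test pointed down while the mean was 0.08 (adjusted p = 0.535). Without Map2k5 the median of the other 13 was -0.09 (adjusted p = 0.0225), an alternative chosen after seeing the data. It was run at the preset correlation only, and Klf2 remained among its members.

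Muscle genes as groups did not pass at day 2.5. The 33 sarcomere genes had a median of -0.01, with Myom2 at -1.10 (adjusted p = 0.0226 with the block) and Actn3 at 0.65 (list adjusted p = 0.282). The 28 genes of myoblast fusion and adhesion had a median of -0.15, with Npnt at -0.72 and Itga7 at -0.64 (list adjusted p = 0.106). Myogenic regulators (median 0.04, adjusted p = 0.106) included Smyd1, which was the 1 member to rise adjusted over the list alone. Excitation-contraction genes (adjusted p = 0.593) and acetylcholine receptor genes (adjusted p = 0.133) had medians of 0.03 and 0.07. Median, mean and test differed in sign for the sarcomere, satellite cell, DNA replication, TCA cycle, inflammatory, insulin-like growth factor and ribosomal protein lists, none of which passed.

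Without dnMEK5 day 2.5 replicate 1, the adjusted p became 0.229 for the Klf and Sp list, 0.452 for immediate early genes, 0.16 for cholesterol synthesis, 0.219 for matrix proteases and 0.0622 for heat shock. Without lacZ day 2.5 replicate 2 it became 0.208 for Klf and Sp factors, 0.324 for immediate early genes and 0.59 for matrix proteases, and the last 2 lists also ended between 0.0505 and 0.0583 without other single arrays.

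At day 4.5 Klf2 again fell, by log2 -3.99 ± 0.27 against lacZ (n = 2 arrays per group, limma adjusted p = 0.00188). Efhd1, a calcium-binding protein of mitochondria, fell by 3.69 ± 0.47 (adjusted p = 0.0422), and Diras2, a small GTPase, by 3.36 ± 0.25 (adjusted p = 0.00296). Serpinb9b fell by 2.16 ± 0.21 (adjusted p = 0.0134) and Klf4 by 1.95 ± 0.26 (adjusted p = 0.0439). Il33, a cytokine of the interleukin 1 family, fell by 1.83 ± 0.15 (adjusted p = 0.00489).

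Smaller falls at day 4.5 were those of Dio2, the deiodinase that activates thyroid hormone (log2 -1.82 ± 0.23), Tppp3, which binds tubulin (-1.65 ± 0.22), Adamtsl5 (-1.25 ± 0.17) and Arf2, a small GTPase (-1.24 ± 0.16), with adjusted p from 0.0422 to 0.0439. Diras2 and Il33 among the falls, and Pappa and Lrrc39 among the rises, had a lower group mean under log2 5, so their sizes are lower bounds. Higher in dnMEK5 cells were Pappa (1.93 ± 0.24, adjusted p = 0.0422), Lrrc39, a protein of the sarcomere's M-band (1.71 ± 0.24, adjusted p = 0.0478), and Pgam2, the muscle form of a glycolytic enzyme (1.37 ± 0.19, adjusted p = 0.0469). Map2k5 stood 7.40 ± 0.23 higher (adjusted p = 8.26e-06). Mapk7 differed by -0.18 ± 0.13 and did not pass. Npnt differed by -0.91 ± 0.25, with an adjusted p of 0.463 that became 0.0203 with the replicate block, the only 1 of 16 alternatives in which it passed. All 5 of its probe sets were negative.

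In total, 4 genes were higher and 13 lower in dnMEK5 cells at day 4.5, and 485 had an unadjusted p under 0.05, where chance alone gives 478.75. With the replicate block 22 were higher and 59 lower, and 1252 had an unadjusted p under 0.05. Each of the 17 differences had the same sign in both experiments, which again follows nearly from passing the test. Map2k5, Klf2 and Diras2 passed in all 16 alternatives, and with only the arrays compared no other named gene passed. Klf4, Efhd1, Dio2, Tppp3, Adamtsl5, Arf2 and Lrrc39 did not pass whichever of the 10 arrays was left out. Over all 16 alternatives adjusted p reached 0.447 for Klf4, 0.422 for Efhd1, 0.426 for Dio2, 0.377 for Tppp3, 0.462 for Arf2 and 0.667 for Lrrc39. It reached 0.819 for Adamtsl5, with the mean of probe sets, and the other probe set of Adamtsl5 was at -0.51. Adjusted p for Il33 became 0.0653 without lacZ day 4.5 replicate 2 and 0.051 without dnMEK5 day 4.5 replicate 2. For Serpinb9b these were 0.0896 and 0.0787, with 0.0548 without lacZ day 4.5 replicate 1. Both Il33 and Serpinb9b were at 0.193 with only the arrays compared. Pappa was at 0.29 without lacZ day 4.5 replicate 2 and passed in 4 of 16 alternatives. Pgam2 was at 0.341 without dnMEK5 day 4.5 replicate 2 and at 0.667 with only the arrays compared, and passed in 2 of 16. The count of lower genes was between 2 and 6 with 1 array left out, 2 without lacZ or dnMEK5 day 4.5 replicate 2.

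**Figure D2:**
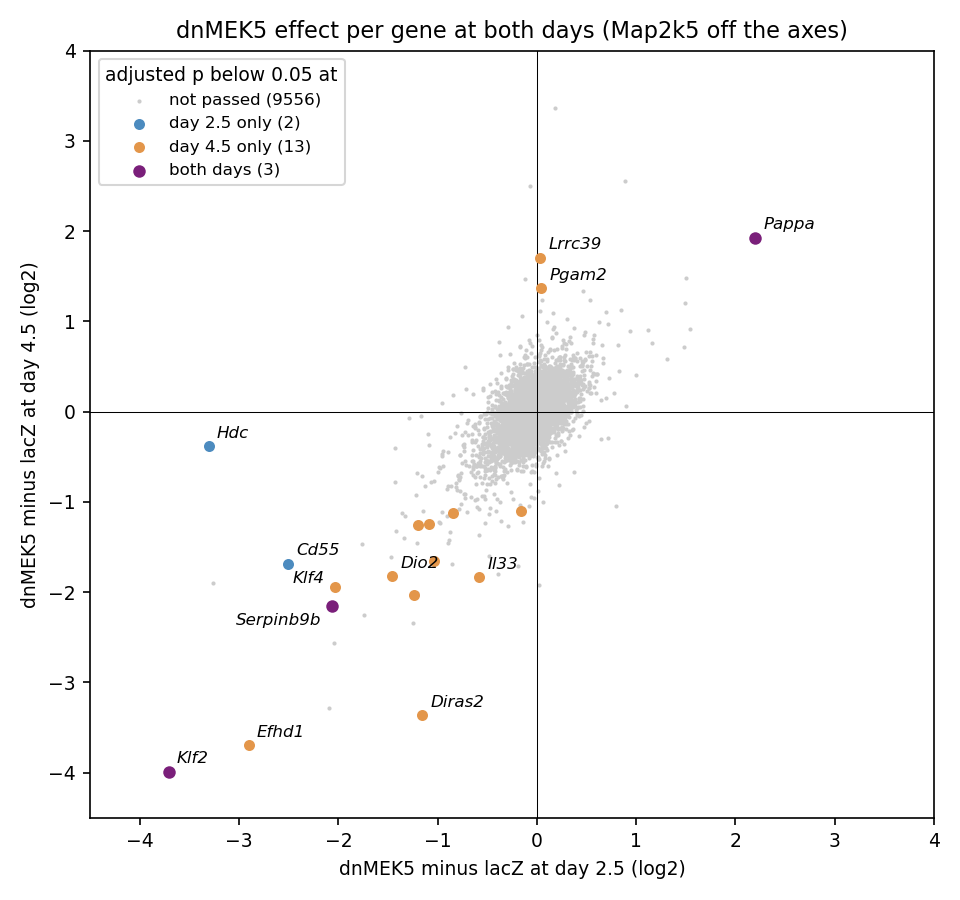
Each point is 1 of the 9575 genes, with the log2 difference of dnMEK5 minus lacZ at day 2.5 (x axis) and at day 4.5 (y axis); colours mark genes with a limma adjusted p below 0.05, and Map2k5 lies off the axes at 7.37 and 7.40. Klf2 is at -3.71 and -3.99, and Hdc at -3.31 and -0.38.

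Of the 17 Klf and Sp factors at day 4.5, Klf2 and Klf4 fell and 15 did not pass; adjusted over the list alone, 2 fell. The median was -0.15, and 14 of 17 differences were negative (camera adjusted p = 0.000134; adjusted p = 0.703 with an estimated correlation). The ERK5 pathway list had 1 member that rose, Map2k5, and 2 that fell, Klf2 and Klf4, counts that were the same adjusted over the list alone. Its median of -0.13 and its test pointed down while the mean was 0.03 (adjusted p = 0.195). Without Map2k5 the median of the other 13 was -0.15 and the camera adjusted p was 0.00163. That alternative was run at the preset correlation only, and Klf2 and Klf4 remained among its members. Mef2c, another member of the ERK5 list, was at -0.74, with -0.98 to -0.60 over its probe sets, and did not pass.

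Sarcomere genes were positive in 26 of 33 cases at day 4.5, with a median of 0.17. None passed over all genes, and adjusted over the list alone 3 rose. Neb was at 0.80, Myh3, the embryonic myosin heavy chain, at 0.76 (adjusted p = 0.0366 with the block) and Actn3 at 0.74, while Myh8, the perinatal form, was negative, at -0.998, and did not pass. The list's adjusted p was 0.00189 (adjusted p = 0.715 with an estimated correlation). The excitation-contraction and calcium genes had a median of 0.05 (adjusted p = 0.694). Pvalb, a calcium buffer of fast fibres, was at least 2.50 higher, from a lacZ mean of 3.52 (adjusted p = 0.184, 0.0201 with the block). Fusion and adhesion genes had a median of -0.12 (adjusted p = 0.13), with Npnt at -0.91, Jam2 at -0.71 and Itga7 at -0.59. Acetylcholine receptor genes had a median of -0.10 while their mean and test were positive (adjusted p = 0.788). Myogenic regulators, Mef2c among them, had medians of -0.03 in experiment 1 and -0.10 in experiment 2, and the list did not pass.

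Oxidative phosphorylation genes were positive in 32 of 34 cases, with a median of 0.17 and Cox8b, a muscle isoform, at 0.85 (adjusted p = 6.77e-05; adjusted p = 0.715 with an estimated correlation). Ribosome biogenesis genes were positive in 18 of 20, with a median of 0.23 and Nop2 at 0.42 (adjusted p = 6.77e-05; adjusted p = 0.703 with an estimated correlation). DNA replication genes were positive in 30 of 35, with a median of 0.17, 0.09 in experiment 1 and 0.30 in experiment 2, and Mcm10 at 0.49 (adjusted p = 0.000839; adjusted p = 0.837 with an estimated correlation). Cholesterol synthesis genes had a median of 0.08, with Mvd at 0.51 (adjusted p = 0.0465; adjusted p = 0.715 with an estimated correlation). Interferon response genes were negative in 12 of 13 cases, with a median of -0.54, -0.82 in experiment 1 and -0.22 in experiment 2, Xaf1 at -1.23 and Irf9 at -1.13 (adjusted p = 0.0011; adjusted p = 0.837 with an estimated correlation). No member of these 5 lists passed, over all genes or adjusted over the list alone.

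Glycolysis had 1 gene that rose, Pgam2, over all genes and adjusted over the list alone (list adjusted p = 0.781). Median, mean and test differed in sign for immediate early, inflammatory, extracellular matrix, insulin-like growth factor, heat shock and neuronal lists, none of which passed. With no filter the adjusted p was 0.171 for sarcomere and 0.0616 for DNA replication genes, and cholesterol synthesis ended with no filter (0.133), quantile normalization (0.0547) and the mean of probe sets (0.0682). Without lacZ day 4.5 replicate 1 the adjusted p became 0.458 for sarcomere and 0.748 for interferon genes, and without dnMEK5 day 4.5 replicate 2 it became 0.4 and 0.204. The DNA replication list ended at 0.585 without dnMEK5 day 4.5 replicate 1 and turned its direction at 0.299 without lacZ day 4.5 replicate 2, while cholesterol synthesis ended between 0.0519 and 0.389 with each of 5 arrays left out.

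**Figure D3:**
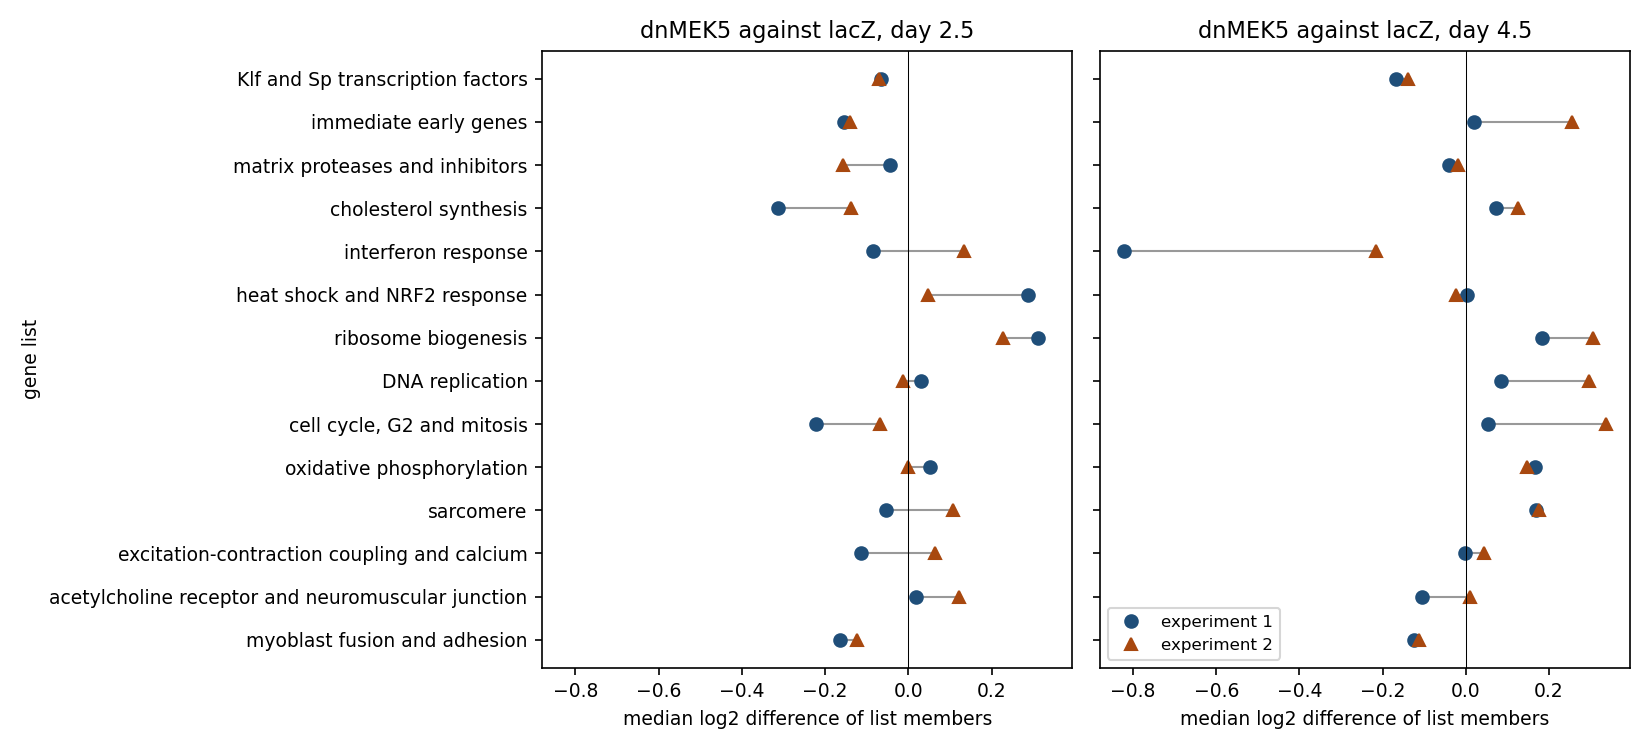
Median log2 difference of dnMEK5 minus lacZ (x axis) over the measured members of 14 gene lists (y axis) at day 2.5 and day 4.5. Circles are experiment 1 and triangles experiment 2; the interferon list at day 4.5 is at -0.82 and -0.22, and the sarcomere list at 0.17 and 0.18.

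The dnMEK5 effects at both days, which share no array, correlated across 9575 genes at Pearson r = 0.656 and Spearman rho = 0.504, a value across genes, which are not independent replicates. Within experiments 1 and 2 Pearson r was 0.558 and 0.551, and between the experiments 0.523 and 0.495. Without Map2k5 it was 0.622. Klf2 and Serpinb9b were lower at both days, and Map2k5 and Pappa higher at both, against 0.00543 and 0.000836 shared genes expected for independent sets. Map2k5 is no sign of agreement, since the virus carried a form of MEK5, which leaves Pappa on the higher side. With the replicate block 25 genes were lower at both days, against 0.216 expected. Calls at both days used 1 estimate of the spread from the same fit, so they are not independent and the expected numbers can be too low.

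The difference of the dnMEK5 effect between the days passed for 0 genes by limma, and 73 genes had an unadjusted p under 0.05, where chance alone gives 478.75. With the replicate block 285 genes had an unadjusted p under 0.05 and 1 gene passed, Hdc, whose effect was 2.92 ± 0.28 higher at day 4.5 than at day 2.5 (adjusted p = 0.0577, 0.0249 with the block). Without lacZ day 4.5 replicate 1 or 2 its adjusted p was 0.0157 and 0.00547, and over 16 alternatives it passed in 3 and reached 0.496. Hdc stood at 6.47 in lacZ cells at day 2.5 and at 3.55 at day 4.5. Next by unadjusted p, none passing, were Lrrc39 (1.67), Pgam2 (1.33), Morrbid (1.15) and Plekhg4 (0.93) among positive differences. On the negative side stood Diras2 (-2.20), Entpd2 (-1.52), Il33 (-1.25), Prr32 (-0.93) and Mob2 (-0.73). For Lrrc39, Pgam2, Entpd2 and Prr32 both group means at day 2.5 lay under log2 5. No effect could be measured there, so their values are not differences between measured effects. Klf2 (-0.27), Klf4 (0.09), Npnt (-0.18), Map2k5 (0.03) and Mapk7 (0.05) did not pass either.

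In lacZ cells, muscle genes rose by day 2.5 of differentiation against growth medium (n = 2 arrays per group, limma). Myog, the myogenic transcription factor myogenin, rose by 8.03 ± 0.19 on the log2 scale, and Mymk, the fusion protein myomaker, by 7.23 ± 0.17 (adjusted p = 1.31e-07 each). Contractile genes also rose, among them Mylpf (8.35 ± 0.29), Tnnc2 (7.70 ± 0.23), Actc1 (7.09 ± 0.17), Myom2 (7.08 ± 0.51), Myl1 (6.64 ± 0.33) and Myh3 (6.56 ± 0.15). Dcn, the matrix proteoglycan decorin, rose by 9.33 ± 0.39, and Selenop, a selenium carrier, by 6.72 ± 0.27. These 10 genes had a day 0 mean under log2 5, so the sizes are lower bounds. Klf2 and Klf4 rose by 2.50 ± 0.27 and 2.42 ± 0.26 (adjusted p = 0.000252 and 0.000232). Npnt (-0.20 ± 0.25), Map2k5 (0.05 ± 0.23) and Mapk7 (-0.00 ± 0.13) did not pass.

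Among the genes that fell by day 2.5 were Lgr6 (-4.95 ± 0.24), a receptor for R-spondins, Selp (-4.90 ± 0.63), Ccnb1ip1 (-4.49 ± 0.34), the chemokine Ccl7 (-4.25 ± 0.25), Fabp7 (-4.05 ± 0.23) and Slco4a1 (-3.78 ± 0.15). Sapcd2 (-3.63), Depdc1b (-3.55), Prr11 (-3.40) and Troap (-3.35) also fell. For 9 of these 10, all but Depdc1b, the lacZ mean was under log2 5, so the falls are lower bounds. In total, 2291 genes were higher and 1800 lower, 1157 and 806 of them by at least 2-fold, and 3279 and 2631 were so with the replicate block.

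Of 33 sarcomere genes at day 2.5, 25 rose, over all genes and adjusted over the list alone, and 8 did not pass (median 3.15, camera adjusted p = 2.01e-12; adjusted p = 0.118 with an estimated correlation). Excitation-contraction genes rose in 16 of 21 cases, with Casq2 at 4.62 and Atp2a1 at 4.35, and 7 of 9 acetylcholine receptor genes rose, with Chrng at 4.41 and Lrp4 at 2.82. Adjusted over the list alone these were also 16 and 7 (list adjusted p = 1.65e-07 and 0.00136; adjusted p = 0.118 and 0.0894 with an estimated correlation). Of 28 fusion and adhesion genes 13 rose, over all genes and adjusted over the list alone, among them Mymk, Mymx, the fusion microprotein myomixer (5.90), Capn3 (2.43) and Itga7 (1.90) (list adjusted p = 0.000713; adjusted p = 0.0873 with an estimated correlation). Of 13 myogenic regulators 6 rose and 1 fell; adjusted over the list alone, 7 rose and 1 fell (adjusted p = 0.0201; adjusted p = 0.386 with an estimated correlation).

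Cell cycle genes fell. All 29 genes of G2 and mitosis fell, over all genes and adjusted over the list alone, with Plk1 at -2.89 and Foxm1 at -2.85 (median -2.22, adjusted p = 7.97e-14; adjusted p = 0.331 with an estimated correlation). Of 35 DNA replication genes 34 fell, also adjusted over the list alone, with Tk1 at -2.45 and Mcm10 at -2.40 (median -1.63, adjusted p = 6.62e-16; adjusted p = 0.162 with an estimated correlation). Of 16 cell cycle arrest and p53 genes 5 rose and 1 fell, also adjusted over the list alone, with Gadd45a at 3.44 and Cdkn1a at 1.79 (list adjusted p = 0.132). Ribosome biogenesis genes fell in 17 of 20 cases (18 adjusted over the list alone), with Nolc1 at -1.81 and Nop56 at -1.78 (adjusted p = 6.6e-09; adjusted p = 0.0873 with an estimated correlation). Of 23 ribosomal protein genes only Rpl14 fell (-0.94), also adjusted over the list alone (list adjusted p = 0.0852).

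Extracellular matrix genes rose in 24 of 30 cases (26 adjusted over the list alone), with Postn at 4.59, Lama2 at 3.54 and Col1a1 at 3.52 (adjusted p = 7.52e-09; adjusted p = 0.0873 with an estimated correlation). Of 13 matrix proteases and inhibitors 8 rose and 1 fell, and of 15 insulin-like growth factor genes 10 rose and 1 fell, with Mmp2 at 2.88, Igf1 at 4.25 and Igf2 at 3.17. These counts were the same adjusted over the list alone (list adjusted p = 0.00734 and 0.00157; adjusted p = 0.138 and 0.118 with an estimated correlation). Of 14 atrophy and proteolysis genes 9 rose, also adjusted over the list alone, with Map1lc3a at 1.97 and Foxo3 at 1.36 (adjusted p = 0.00144; adjusted p = 0.0894 with an estimated correlation). Fibroblast markers rose in 6 of 9 cases and fell in 1, also adjusted over the list alone, with Mfap5 at 6.51 and Dpt at 3.70 (adjusted p = 0.013; adjusted p = 0.138 with an estimated correlation). Of 21 TGF-beta and BMP genes 8 rose and 6 fell, also adjusted over the list alone, with Bmp4 at 3.15 and Id2 at -2.28 (list adjusted p = 0.437).

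Of 13 interferon response genes 5 rose (7 adjusted over the list alone), with Gbp2 at 4.10 and Xaf1 at 3.25 (list adjusted p = 0.0191; adjusted p = 0.564 with an estimated correlation), and 10 rose with the replicate block. The list's median was 2.28 in experiment 1 and 0.97 in experiment 2. Cholesterol synthesis genes rose in 9 of 20 cases and fell in 1, with Tm7sf2 at 2.00 and Insig1 at 1.26 (adjusted p = 0.0473; adjusted p = 0.386 with an estimated correlation). Heat shock and NRF2 genes fell in 5 of 16 cases, with Gsr at -1.82 (adjusted p = 0.00646; adjusted p = 0.331 with an estimated correlation). Glycolysis genes fell in 7 of 15, with Ldha at -0.90 (adjusted p = 0.0246; adjusted p = 0.564 with an estimated correlation). The counts of these last 3 lists were the same adjusted over the list alone. Oxidative phosphorylation genes fell in 8 of 34 (6 adjusted over the list alone) and 1 rose, with Cycs at -0.92 (adjusted p = 0.0207; adjusted p = 0.47 with an estimated correlation).

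Lists that did not pass at day 2.5 had these counts. Klf and Sp factors had 5 members that rose and 2 that fell (list adjusted p = 0.296), the ERK5 list 6 and 2 (0.414), TCA cycle and fatty acid genes 0 and 4 (0.151), and satellite cell markers 4 and 6 (0.484). Inflammatory genes had 3 and 4 (0.346), unfolded protein response genes 4 and 2 (0.518), smooth muscle markers 3 and 1 (0.112), and adipocyte markers 1 and 4 (0.0729). Immediate early genes had 3 and 2 (0.823), osteoblast and chondrocyte markers 1 and 0 (0.174), endothelial markers 0 and 0 (0.485), and neuronal markers 2 and 1 (0.823), with a median of -0.50 and a positive mean of 0.22. Adjusted over the list alone, 5 satellite cell markers rose, 5 inflammatory genes and 3 immediate early genes fell, and the other counts were the same.

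Processing choices and single arrays ended some list calls at day 2.5. With no filter the adjusted p was 0.134 for glycolysis, 0.227 for oxidative phosphorylation and 0.111 for heat shock and NRF2 genes. With quantile normalization it was 0.0514 for glycolysis and 0.0661 for oxidative phosphorylation, and with the mean of probe sets 0.0752 for myogenic regulators. Without growth medium day 0 replicate 1 the adjusted p was 0.078 for myogenic regulators, 0.118 for glycolysis and 0.176 for oxidative phosphorylation. Without lacZ day 2.5 replicate 1 it was 0.12 for interferon and 0.0796 for cholesterol genes, without replicate 2 it was 0.115 for glycolysis and 0.0511 for oxidative phosphorylation, and without growth medium day 0 replicate 2 it was 0.0507 for interferon and 0.148 for cholesterol genes.

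By day 4.5 the muscle genes of lacZ cells stood higher still against day 0. Tnnc2 rose by 11.30 ± 0.23, Mylpf by 11.07 ± 0.29, Mymk by 10.61 ± 0.17, Myog by 10.31 ± 0.19 and Tnni1 by 10.09 ± 0.15 on the log2 scale (n = 2 arrays per group, limma adjusted p from 1.04e-08 to 7.19e-08). Myl1 (9.82), Actc1 (9.70), Tnni2 (9.69), Myh3 (9.59) and Dcn (9.51) also rose. The day 0 means of these 10 genes were under log2 5, so the sizes are lower bounds. Klf4 and Klf2 rose by 2.41 ± 0.26 and 2.37 ± 0.27, and Npnt by 1.15 ± 0.25 (adjusted p = 0.00602). Map2k5 (-0.10) and Mapk7 (-0.13) did not pass.

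Nefl, a neurofilament subunit, fell by day 4.5 (-5.34 ± 0.68), as did the chemokines Ccl7 (-5.12 ± 0.25) and Ccl2 (-4.94 ± 0.29). Selp (-4.91), Ccnb1ip1 (-4.67), Depdc1b (-4.53), Lgr6 (-4.52), Fabp7 (-4.03), Prr11 (-3.99) and Car8 (-3.99) also fell. For 9 of these 10, all but Ccl2, the lacZ mean was under log2 5, so the falls are lower bounds. In total, 2239 genes were higher and 2141 lower, 1198 and 949 of them by at least 2-fold, and 3088 and 3055 were so with the replicate block.

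Sarcomere genes rose in 32 of 33 cases at day 4.5 (33 adjusted over the list alone; median 7.49, adjusted p = 7.65e-26; adjusted p = 0.0533 with an estimated correlation). Excitation-contraction genes rose in 18 of 21 and fell in 1, with Ckm at 7.85, and all 9 acetylcholine receptor genes rose, with Chrng at 7.65; these counts were the same adjusted over the list alone (list adjusted p = 7.88e-14 and 3.1e-06; adjusted p = 0.0533 each with an estimated correlation). Fusion and adhesion genes rose in 16 of 28 and fell in 2, also adjusted over the list alone, with Mymx at 8.42 and Cav3 at 3.04 (adjusted p = 0.000668; adjusted p = 0.0533 with an estimated correlation). Myogenic regulators rose in 7 of 13 and fell in 2, also adjusted over the list alone, with Mef2c at 7.21 and Smyd1 at 6.13 (adjusted p = 0.00323; adjusted p = 0.28 with an estimated correlation). All 29 G2 and mitosis genes and all 35 DNA replication genes fell, also adjusted over the list alone (medians -3.07 and -2.01, adjusted p = 1.76e-14 and 5.43e-16; adjusted p = 0.295 and 0.182 with an estimated correlation).

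Matrix genes rose in 21 of 30 cases at day 4.5 (23 adjusted over the list alone; adjusted p = 9.29e-08, adjusted p = 0.0533 with an estimated correlation), with Postn at 6.13. Ribosome biogenesis genes fell in 14 of 20 (16 adjusted over the list alone; adjusted p = 1.28e-05, adjusted p = 0.101 with an estimated correlation). Smooth muscle markers rose in 6 of 9, and adjusted over the list alone 1 also fell (adjusted p = 0.0192; adjusted p = 0.313 with an estimated correlation). Unfolded protein response genes rose in 6 of 19, also adjusted over the list alone, with Dnajb9 at 2.12 (adjusted p = 0.0192; adjusted p = 0.395 with an estimated correlation). Interferon genes rose in 3 of 13, also adjusted over the list alone, and in 9 with the replicate block (adjusted p = 0.0714, 0.0474 with the block). Of 16 cell cycle arrest and p53 genes 7 rose and 2 fell (adjusted p = 0.0192; adjusted p = 0.401 with an estimated correlation), with Gadd45a at 3.79 and Cdkn1a at 2.96. Matrix proteases rose in 9 of 13 and fell in 1 (0.00482; 0.134 with an estimated correlation), and insulin-like growth factor genes rose in 9 of 15 and fell in 1 (0.00323; 0.134 with an estimated correlation), with Igf2 at 7.02. Atrophy genes rose in 8 of 14 and fell in 1 (0.000748; 0.0597 with an estimated correlation), with Trim63 at 4.67. Heat shock and NRF2 genes fell in 7 of 16 and rose in 1 (0.0163; 0.326 with an estimated correlation), with Gsr at -2.08. The counts of these 5 lists were the same adjusted over the list alone. Ribosomal protein genes fell in 4 of 23, and in 0 adjusted over the list alone (0.0281; 0.336 with an estimated correlation). For glycolysis the median was -0.05 and the mean 0.14, and Pgam2 rose by 4.59 (list adjusted p = 0.532). Without lacZ day 4.5 replicate 1 the unfolded protein and smooth muscle lists ended at 0.064 and 0.0511, and the arrest list at 0.0827. Ribosomal proteins ended at 0.131 with quantile normalization, 0.0504 with the mean of probe sets, 0.0803 without growth medium day 0 replicate 1 and 0.073 without lacZ day 4.5 replicate 2. Heat shock and NRF2 genes ended at 0.0507 with no filter, and fibroblast markers (0.0613 with all arrays) passed with each of 4 arrays left out. Without lacZ day 4.5 replicate 2 the interferon list passed at 0.00609, as it did at 0.0371 without either lacZ day 2.5 array; over 16 alternatives it passed in 4 and reached 0.653.

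**Figure D4:**
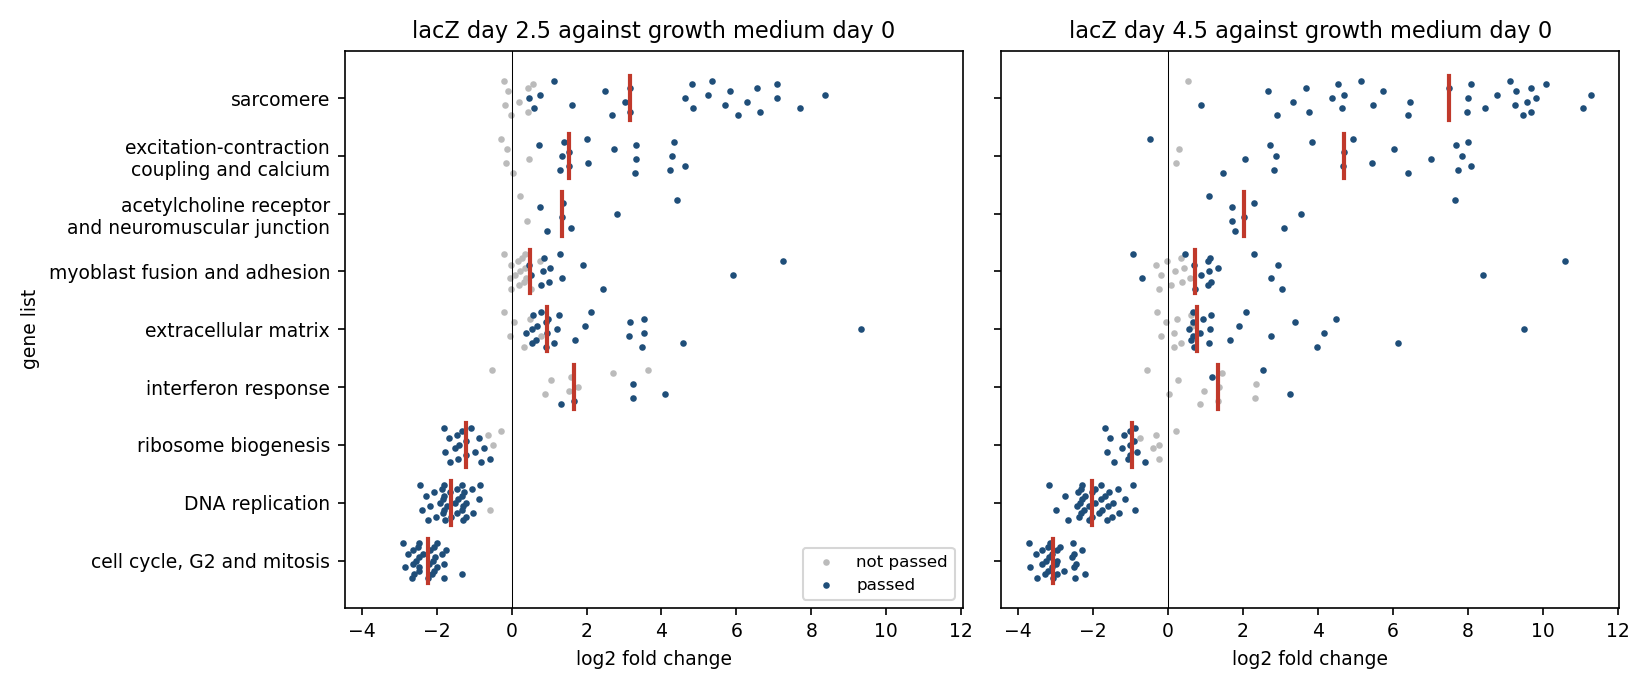
Log2 fold change (x axis) of each measured member of 9 gene lists (y axis) in lacZ cells at day 2.5 and day 4.5 against growth medium at day 0. Points are genes, blue where the limma adjusted p was below 0.05, and red lines are list medians, which go from 3.15 to 7.49 for the sarcomere list.

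Between day 2.5 and day 4.5 of lacZ cells (n = 2 arrays per group), Myh8, a myosin heavy chain, rose by 6.60 ± 0.31 and Mef2c, a muscle transcription factor, by 5.93 ± 0.39, followed by Dhrs7c (5.80 ± 0.19), Ctrb1 (5.77 ± 0.30) and Tceal7 (5.74 ± 0.25), with limma adjusted p from 2.43e-06 to 5.23e-05. These rises are lower bounds, as the day 2.5 means were under log2 5, and so are the falls of Nefl and Hdc. Npnt rose by 1.35 ± 0.25 (adjusted p = 0.0199). Nefl (-3.88 ± 0.68), Ifitm1 (-3.02 ± 0.36), Hdc (-2.92 ± 0.20), Blnk (-2.52 ± 0.36) and the chemokine Cxcl1 (-2.30 ± 0.29) fell. Klf2 (-0.14), Klf4 (-0.01), Map2k5 (-0.15) and Mapk7 (-0.12) did not pass. In total, 302 genes were higher and 207 lower, and 794 and 1214 with the replicate block.

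Sarcomere genes rose in 31 of 33 cases between the days (32 adjusted over the list alone), excitation-contraction genes in 17 of 21 (17) and acetylcholine receptor genes in 6 of 9 (7), each with an adjusted p of 0.0144 with an estimated correlation. Inflammatory genes fell in 4 of 11 (6 adjusted over the list alone), with Ccl2 at -1.94 (adjusted p = 0.000569; adjusted p = 0.279 with an estimated correlation). All 29 G2 and mitosis genes had negative differences, with a median of -0.13 in experiment 1 and -1.28 in experiment 2 (-0.71 over both), and none passed, over all genes or adjusted over the list alone (list adjusted p = 5.65e-06; adjusted p = 0.52 with an estimated correlation). DNA replication genes had a median of -0.11 in experiment 1 and -0.59 in experiment 2 (-0.42 over both), and none passed either way (0.00014; 0.52 with an estimated correlation).

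Other lists that passed between the days had small member counts. Myogenic regulators rose in 5 of 13 (adjusted over the list alone 7 rose and 3 fell; adjusted p = 0.00014, 0.279 with an estimated correlation), with Smyd1 at 3.74. Fusion and adhesion genes rose in 6 of 28 and fell in 2 (7 and 4 adjusted over the list alone; medians 0.01 and 0.14 in experiments 1 and 2; 0.0493, 0.279 with an estimated correlation), with Mymk at 3.37 and Cav3 at 3.09. Oxidative phosphorylation genes rose in 2 of 34 (3; 5.24e-06, 0.279 with an estimated correlation), with Cox6a2 at 4.51, and glycolysis genes in 2 of 15 (4; 0.0129, 0.544 with an estimated correlation), with Pgam2 at 4.65. Cell cycle arrest genes rose in 3 of 16 (3; 0.0157, 0.485 with an estimated correlation) and unfolded protein response genes in 3 of 19 (3; 0.000569, 0.318 with an estimated correlation), with Chac1 at 2.11. Ribosome biogenesis genes rose in 1 of 20 (1; 0.00014, 0.271 with an estimated correlation), smooth muscle markers in 1 of 9 (1; 0.0157, 0.348 with an estimated correlation), and neuronal markers fell in 3 of 6 (4; 0.00585, 0.348 with an estimated correlation). Counts in brackets are adjusted over the list alone. Satellite cell markers (0.0792) and TCA cycle genes (0.0893) did not pass, and did so with the replicate block, at 0.0498 and 0.0364. Satellite cell markers passed in 3 of 16 alternatives and TCA cycle genes in 1. The fusion list ended at 0.555 with no filter, at 0.0716 with quantile normalization and between 0.0556 and 0.171 with each of 6 arrays left out. With no filter the arrest, glycolysis, inflammatory and neuronal lists also ended, at 0.0666, 0.0656, 0.0886 and 0.0725. Without lacZ day 2.5 replicate 2 the arrest, glycolysis and smooth muscle lists ended at 0.171, 0.182 and 0.182, and without lacZ day 4.5 replicate 1 at 0.247, 0.225 and 0.173. DNA replication ended at 0.237 without lacZ day 4.5 replicate 2.

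The G2 and mitosis list between the days ended at 0.0781 without lacZ day 4.5 replicate 2. Without lacZ day 2.5 replicate 2 the calls of Blnk (adjusted p = 0.056) and Nefl (0.13) ended, the counts were 159 and 19, and Npnt was at 0.104; Npnt was at 0.113 without lacZ day 2.5 replicate 1 and 0.117 without lacZ day 4.5 replicate 2. With no filter and with only the arrays compared Npnt was at 0.0667 and 0.0546, and Nefl at 0.0762 and 0.0749.

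Of the 13 genes lower with dnMEK5 at day 4.5, 12 had risen in lacZ cells by day 2.5, against 3.11 expected for independent sets, in comparisons that share no array. The exception was Prr32, which the naming rule gave for the difference of effects but not for dnMEK5 against lacZ at day 4.5. With the replicate block 44 of 59 had risen, against 20.2 expected, and 3 had fallen, against 16.2 expected. Genes higher with dnMEK5 at day 4.5 showed no such excess with the block. Of 22, 7 had risen, against 7.53 expected, and 6 had fallen, against 6.05 expected. Of the 4 genes lower at day 2.5, 3 had risen by day 4.5, against 0.935 expected. The calls of a fit shared 1 estimate of the spread, so these expected numbers can be too low.

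Across 9575 genes, which are not independent replicates, the change at day 2.5 and the dnMEK5 effect at day 4.5 had a Pearson r of -0.337 and a Spearman rho of -0.400. Within experiments 1 and 2 r was -0.243 and -0.361. It fell in size to -0.223 without dnMEK5 day 4.5 replicate 1 and to -0.166 without lacZ day 4.5 replicate 2. The change at day 4.5 and the dnMEK5 effect at day 2.5 had r = -0.103 and rho = -0.121, with -0.154 and -0.0473 within experiments. Without dnMEK5 day 2.5 replicate 1 that r was -0.0192. Pairs of the same day share the lacZ arrays, and their r was -0.221 and -0.238. Simulated unchanged groups gave -0.502 and -0.496, but they held no differentiation change, so these r values cannot be compared in size. The covariances of the same-day pairs, -0.0506 and -0.0801, exceeded the simulated -0.0108 and -0.0106 in size.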

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

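All tests of an explanation in this part were chosen after the result was seen. The interaction contrast behind the list and gene differences was fixed before.

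By the interaction contrast, the difference of the dnMEK5 effect between the days passed for Hdc only with the replicate block or without a lacZ day 4.5 array, and for 8 gene lists only by camera at the preset correlation. Each of the 8 list calls was lost with an estimated correlation, with adjusted p from 0.201 to 0.739, and with fry. The myogenic call was also lost with the mean of probe sets (0.108) and the sarcomere call with no filter (0.0819). Neuronal markers did not pass (adjusted p = 0.0754); they passed with the block (0.0378) and with each of 4 arrays left out, 5 of 16 alternatives that ranged from 0.000721 to 0.983. The median difference, day 4.5 minus day 2.5, was -0.15 for myogenic regulators, 0.19 for sarcomere genes, 0.34 for G2 and mitosis genes and 0.17 for DNA replication genes. It was 0.31 for cholesterol synthesis, 0.13 for oxidative phosphorylation, -0.69 for interferon response and -0.18 for heat shock and NRF2 genes. Each of these calls except that of heat shock and cholesterol synthesis ended without at least 4 of the 8 infected arrays left out singly; heat shock ended at 0.152 without dnMEK5 day 2.5 replicate 1, and cholesterol synthesis in none.

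Hdc stood out with a difference of 2.92 between the days. Its mean was 6.47 in lacZ cells at day 2.5 and 3.55 at day 4.5, against 3.19 at day 0. A lack of room to fall may account for the smaller effect at day 4.5: the lacZ mean at day 4.5 lay only 0.38 above the mean of dnMEK5 cells at day 2.5. This test could not tell a floor of the array from a gene that had returned to its low level, since both give values near 3.

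The interferon list had medians of -0.82 and -0.22 with dnMEK5 at day 4.5 in experiments 1 and 2 (camera adjusted p = 0.0011; adjusted p = 0.837 with an estimated correlation), and the call was also lost with fry. Variation between cultures might account for the values: the difference between experiments within the 5 groups had an SD of 0.596, and the mean effect was -1.23 standard errors from 0. That leaves culture variation and an effect of dnMEK5 unseparated, and a different response to the 2 viruses was not tested, as no array measured infection.

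Of the 13 genes lower with dnMEK5 at day 4.5, 12 were genes that had risen with differentiation. Arrays shared by both comparisons are not a likely source, because the fold changes behind the overlap of 12 came from separate arrays. The calls, however, shared 1 estimate of the spread. Genes of low spread pass more easily in both, so the 3.11 expected for independent sets can be too low. A shared spread has no direction, and 0 of the 13 had fallen by day 2.5, against 2.44 expected. The level of expression alone is not a likely source either. Sets of 13 genes matched on the lacZ level at day 4.5 were drawn 10000 times. Over the central 95% of draws the upper limit was 6 genes that had risen, and the highest draw held 10. These sets were not matched on the spread. Differentiation held back as a whole would place sarcomere genes below 0, and their median was 0.17, with 0.17 in experiment 1 and 0.18 in experiment 2. That speaks for this list only. In experiments 1 and 2 the medians were -0.12 and -0.11 for fusion and adhesion genes and -0.03 and -0.10 for myogenic regulators. Excitation-contraction genes lay at -0.002 and 0.04, and acetylcholine receptor genes at -0.11 and 0.01. A partial delay of differentiation is thus not excluded. A block of a part of the differentiation program stays open as a hypothesis, as does a response to infection that dnMEK5 weakens, because no uninfected cells at days 2.5 and 4.5 were used here.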

How the results depend on the processing

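The 3 alternatives that leave out Map2k5 were chosen after seeing the data; all others were fixed before. The replicate block changed no call of a list or named gene besides those given in the results above. It also raised many counts of list members, which are given only in part, and every gene that passed without it passed with it in the same direction. For genes higher with dnMEK5 at day 2.5 (2) the count was 4 with the block, and 1 with no filter, a log2 floor of 7, the mean of probe sets, only the arrays compared or the ratio table. For lower genes (4) it was 35 with the block, and 1 with no filter or only the arrays compared. At day 4.5 the higher count (4) was 22 with the block, 2 with no filter, a floor of 7 or each probe set by itself, and 1 with the mean of probe sets, trend and robust, only the arrays compared or the ratio table. The lower count (13) was 59 with the block, 7 with no filter, 8 with each probe set by itself, 2 with only the arrays compared and 5 with the ratio table. Only the arrays compared leave fewer degrees of freedom; for the others, the ratio table among them, the cause was not tested. The ratio table raised the counts against day 0, to 3061 higher and 2488 lower at day 2.5 and 2895 and 2924 at day 4.5. With each probe set by itself, where more items are tested, the counts were 3807 higher and 3190 lower for lacZ day 2.5 against day 0, 3745 and 3691 for day 4.5, and 466 higher between the days. A 2-fold minimum gave 1157 and 806, 1198 and 949, and 65 lower between the days. Between the days the block gave 794 higher and 1214 lower, and only the arrays compared gave 72 lower. For the difference of the dnMEK5 effect, the block gave 1 higher gene (Hdc) and no filter 1 lower (Prr32). Leaving out 1 array in turn, with the lone array assumed to vary like the others, gave 1 to 3 higher and 2 to 3 lower at day 2.5, 1 to 2 higher and 2 to 6 lower at day 4.5, and 159 to 290 higher and 19 to 174 lower between the days. It gave 0 to 2 higher for the difference of effects, 2 without lacZ day 4.5 replicate 1 (Hdc and Usp17la). The r of 0.656 between the days was 0.602 with no filter, 0.714 with a floor of 7, 0.647 with the mean of probe sets, 0.622 without Map2k5 and 0.490 to 0.656 with 1 array left out, lowest without dnMEK5 day 2.5 replicate 1. The relations to differentiation ranged from -0.384 to -0.166 and from -0.135 to -0.0192 with 1 array left out. Adjusted p of lists whose direction turned with 1 array left out ranged from 2.35e-05 to 0.778 for interferon genes at day 2.5, from 1.27e-12 to 0.261 and 4.65e-13 to 0.585 for G2 and mitosis and DNA replication genes at day 4.5, and from 2.26e-20 and 3.74e-14 to 0.969 for the same lists in the difference of effects. In these alternatives, which apart from the block itself were fitted without it, the dnMEK5 calls were far less stable than those of differentiation. Leaving out single arrays was not repeated with the block, so stability under the paired fit is not known. Over all alternatives, 230 values of called dnMEK5 lists, the difference of effects included, stayed past the threshold in the same direction, 102 did not and 4 turned, and for differentiation lists 700 stayed and 100 did not. All 21 called dnMEK5 lists were lost with fry, and all 21 with an estimated correlation; of 50 differentiation lists 7 and 47 were lost. For dnMEK5 named genes that passed, 162 values stayed and 158 did not, with 115 of the losses on leaving out 1 array and 15 with only the arrays compared. For differentiation genes 887 stayed and 9 did not. No normalization shifted the median of all genes by over 0.1. Signal near background limits the rest: fewer than 40% of probe sets were at or above the floor.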

Other observations

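The genes named in this part were chosen here after their values were seen, and its dnMEK5 comparisons had been fixed before. The comparison of experiment 2 with experiment 1 was not among the comparisons fixed before. Several genes passed with the replicate block and not without it. The neurofilament genes Nefl and Nefm were 3.37 and 2.56 higher in dnMEK5 cells at day 4.5 (blocked limma adjusted p = 0.0124 and 0.00194). Nefl had mean log2 intensities of 9.42 at day 0, 7.96 in lacZ cells at day 2.5 and 4.08 at day 4.5, and 7.44 in dnMEK5 cells at day 4.5. The microtubule proteins Map2 and Mapt were at -1.24 and -1.27 (0.0187 and 0.039). Of the matrix genes named here, Dcn (-2.34, 0.027), Prg4 (-2.25, 0.0195) and Ecm1 (-0.60, 0.0454) were lower, as was Npnt, given above. Dpt also passed (-1.37, 0.0233), but both its means, 4.84 in lacZ and 3.47 in dnMEK5 cells, lay under log2 5. No effect could be measured for Dpt. Smoc2 (1.02, 0.0209) was higher, and the fixed matrix list had a median of 0.02 and did not pass. Also lower were Mgam, a gut-type maltase (-3.28, 0.00161), and, at day 2.5, Has1, a hyaluronan synthase (-3.26, 0.0107). For Nefl, Nefm, Mapt, Prg4 and Has1 the lower group mean was under log2 5, so their sizes are lower bounds.

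Among muscle genes, Smyd1 passed with the block at both days (1.16 and 0.76), and Trim54, a sarcomere-associated ubiquitin ligase (0.72), Myh3 (0.76) and Myom1 (0.63) passed at day 4.5. In the other direction, Sorbs2, an adaptor protein of the sarcomere's Z-disc, was lower at both days (-1.13 and -0.82, 0.00761 and 0.0162), and Myom2 at day 2.5 (-1.10, 0.0226). The experiments themselves differed: with the block, 1931 genes were higher and 1879 lower in experiment 2 among 9575. The interferon-induced genes Ifit1 (-2.44) and Oasl2 (-2.02) and the chemokine Ccl5 (-1.58) were lower in experiment 2, and Gsta2, a glutathione transferase, was 1.81 higher. The interferon list was higher in experiment 1 by a median of 1.56 in lacZ cells at day 2.5 and by 0.02 at day 0.

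Not all probe sets of Map2k5 followed dnMEK5. Besides the probe set used, 1 was 8.73 and 8.66 higher in dnMEK5 cells at days 2.5 and 4.5, while another differed by -0.11 and 0.06.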
